A study of Mus musculus with 18 samples.

How the data were processed

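Meniscus tissue of mice was kept in culture for 3 weeks, either in a rotating wall vessel bioreactor, which simulates microgravity (SMG), or under static conditions at normal gravity. Wild-type C57Bl/6 mice and CD36 knockout mice of both sexes were used. All menisci of a mouse were pooled, so each of the 18 libraries stands for 1 mouse, per the labels' protocols, and the tests treat the libraries as independent. The titles call the replicate numbers donors, and the numbers in the library names differ from these: 5 and 6 occur in both female static and female SMG wild type. Whether a number marks an animal or litter shared between cultures is not given in the sources used here. Total RNA was sequenced on an Illumina NextSeq 2000. The 6 groups, by the sample titles, were female and male static wild type (n = 3 each), female and male SMG wild type (n = 3 each), female SMG knockout (n = 4) and male SMG knockout (n = 2). No static knockout sample was analysed here, so genotypes could be compared only under SMG.

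Per the labels' protocols, reads were processed in Partek Flow 12.5.0: bases under Phred 20 were trimmed from the 3′ end, reads were aligned to mm39 with STAR 2.7.8a, and genes of GENCODE M35 were quantified with Partek's E/M algorithm, which can share a read between genes. Whether counting used strand is not given in the sources used here. Per the submitters' processing notes, limma and Partek were used, with no version given. The deposited values are on a log2 scale. Their form was inferred from the values: log2 of RPM, reads scaled to a library total of 1000000, computed by the authors with 0.5 reads added before division by a scaled library size. Each library had its own lowest value, the one that 0 reads give under this form, and the next steps lay where 1 and 2 reads put them. On this form the libraries held 7348682 to 11552873 estimated reads, with scaling factors between 0.906 and 1.074. Of the values below 20 reads, 41.1% to 47.5% per library were whole within 0.01 reads, so the reads are estimates and no count model was used. The 10 most abundant genes took a median of 15.4% of a library's reads. How the authors filtered genes or set the scaling is not given in the sources used here.

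The table held 23012 genes by Ensembl identifier. Of these, 22894 (99.5%) were found in GENCODE M39, an annotation of the same genome build, which gave symbols, biotypes and mm39 coordinates. Genes with a mean of at least 0.5 RPM over the 18 libraries were tested, 19367 in all, of which 14043 are protein coding. Reads near the floor carry little precision: with 0.5 reads added before the log, a fold of a gene with few reads is compressed, so estimated read sums are given for many such genes.

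The test was limma-trend (limma 3.58.1 in R 4.3.3): lmFit with 6 group means over all 18 libraries and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan foresaw normalized values on a linear scale with a pseudocount of 1. It also provided for values already on a log scale to be used as they are, which was done, and no pseudocount was added. The 11 comparisons were SMG against static wild type (mean of both sexes, females, males, and the difference between the sexes), knockout against wild type under SMG (the same 4), and females against males in each condition (3). Where n is 3 or fewer the spread comes mainly from the other groups, which the fit assumes to vary alike. Log2 differences are given with their standard error (SE), and group levels with the SD.

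The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. For the comparisons averaged over sex, the 12 genes with the largest increase and the 12 with the largest decrease were named, and for the others 5 and 5. They were taken among genes past the threshold whose libraries do not overlap between the groups compared, leaving out predicted genes, pseudogenes and clone-style symbols. Up to 4 members past the threshold were named per list, and where none passed, up to 2. The 26 lists covered matrix, inflammatory, metabolic, stress and signalling genes, markers of other cell types, a sex chromosome check and the chromosomal neighbours of Cd36. Lists with at least 5 measured members (24) were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison. Of the 12 lists called between SMG and static, and of every other list call in the 11 comparisons (107 in all), none passed with the correlation estimated from the residuals. List calls therefore describe these libraries under the preset correlation only. The 4 further lists, chosen after seeing the data, are described with the observations that led to them.

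Alternatives planned beforehand were 2 pseudocounts (0.1 and 10, added to the RPM), no filter and a filter 5 times stricter (2.5 RPM), median-of-ratios scaling, quantile normalization, robust eBayes, sample quality weights, only the groups compared in the fit, the replicate number as a block, the sex given by the library name, and leaving out each library in turn. Alternatives added after seeing the data were voom weights, leaving out the 3 libraries lowest on the first principal component, marker scores of 3 cell types as covariates, removal of each library's trend with gene span, and a second estimator of sample weights.

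The test was checked on simulated data with 19367 genes and known changes. With independent noise (20 draws), genes given a log2 change of 1 were recovered in 53.8% of cases for SMG against static averaged over sex, 32.6% in females, 33.4% in males and 50.4% for the knockout averaged over sex. For a log2 change of 2 the shares were 81.6%, 68.2%, 66.2% and 80.3%. Changes of 1 were thus missed in many cases at these group sizes. When whole-library deviations were reassigned among libraries (100 draws), the median number of false calls was 0, 1, 0 and 0 for the same 4 comparisons, with means of 8.2, 23.9, 3.5 and 16.2 and highest values of 239, 1859, 60 and 1219, so structure shared by libraries can at times give many false calls. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.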

Results

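Gene expression was measured by RNA sequencing in cultured mouse meniscus, the fibrocartilage pad of the knee, in 18 libraries of 1 mouse each. Wild-type cultures were static or in simulated microgravity (SMG), each of 3 females and 3 males. Knockout mice lacking CD36, a membrane receptor that takes up fatty acids and oxidized lipids, were cultured under SMG only, 4 titled female and 2 titled male. The deposited values are log2 RPM (reads scaled to a library total of 1000000). Libraries of a group correlated across genes with Pearson's r between 0.881 and 0.977, and no pair was close enough to be one library deposited under 2 names. The first principal component carried 29.7% of the variance and did not follow the groups. Its 3 lowest libraries were female static wild-type replicate 2, male static wild-type replicate 3 and female knockout replicate 3. On the next (13.4%) static libraries lay at 20.1 to 54.5 and SMG libraries, knockout included, at -66.2 to 0.3.

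Cd36 itself (ENSMUSG00000002944, mm39 chromosome 5, 17986432 to 18094067) was read first, as a check of the labels. Its log2 RPM was 8.36 ± 0.41 (SD, n = 3) in female and 8.71 ± 0.72 (n = 3) in male wild-type SMG libraries, and 5.50 ± 1.13 (n = 4) in female and 4.53 ± 1.06 (n = 2) in male knockout libraries. Static wild-type libraries held 7.52 ± 1.24 (n = 3) in females and 6.98 ± 0.18 (n = 3) in males. Averaged over sex, knockout libraries were lower than wild-type SMG libraries by limma, with a log2 difference of -3.52 ± 0.47 (SE) and an adjusted p of 0.00676, and no knockout library reached any wild-type SMG library. Reads were not absent from the knockout: the 6 libraries kept 13.7 to 77.4 RPM, and the highest, at a log2 of 6.27, exceeded female static wild-type replicate 2 at 6.08. The values are sums over the whole gene, and the part of the gene removed is not given in the sources used here, so they cannot show whether the remaining transcripts encode a protein.

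The sex of 5 of the 6 knockout libraries is given differently by the title and by the library name. Xist, the RNA that silences an X chromosome in female cells, had a log2 RPM of 10.62 to 12.11 in the libraries titled female and -1.64 to 0.67 in those titled male. Ddx3y, Kdm5d, Eif2s3y and Uty, which lie on the Y chromosome, summed to at most 1 estimated read in any library titled female and to at least 2348 in any titled male. The title matched these genes in 18 of 18 libraries and the library name in 13. The titles are used throughout.

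**Figure D1:**
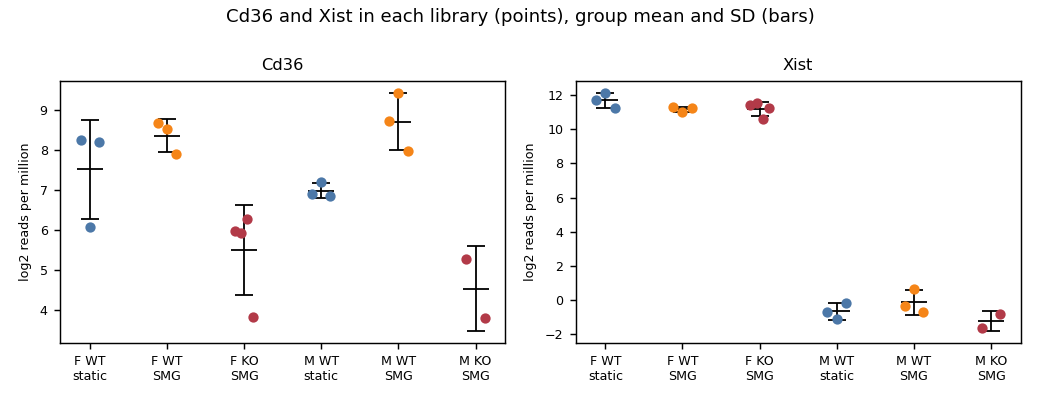
Log2 RPM of Cd36 and of Xist in each of the 18 libraries by group, with points for libraries and bars for the group mean ± SD. Cd36 in the knockout libraries lies between 3.78 and 6.27 and in wild-type SMG libraries between 7.89 and 9.42, and Xist is above 10 in every library titled female and below 1 in every library titled male.

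SMG was compared with static culture in wild-type mice after 3 weeks. The cultures differ in the vessel and its rotation as well as in simulated gravity. No rotated culture at normal gravity is among the 6 groups, so the changes cannot be assigned to gravity loading alone. Averaged over both sexes, the genes with the largest decreases included Kcnc1, a voltage-gated potassium channel, at a log2 change of -5.55 ± 0.68 (SE, 6 against 6 libraries), and Matn1, the cartilage matrix protein matrilin 1, at -4.74 ± 0.70. Their estimated reads, summed over 3 libraries, went from 1249 to 12.5 in females and from 690 to 34.5 in males for Kcnc1, and from 759.5 to 12.5 and from 471.5 to 55.5 for Matn1. Increases included Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, at 4.52 ± 0.52, and Hspa1b, an inducible heat shock protein, at 2.05 ± 0.22. Cyp1a1 went from 11 to 195.5 estimated reads in females and from 4.5 to 136.5 in males. By limma the adjusted p was 0.000865 for Kcnc1, 0.00246 for Matn1, 0.000638 for Cyp1a1 and 0.000613 for Hspa1b.

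Further decreases were seen in Tcap (-3.81), a titin-binding protein of muscle, Cilp2 (-3.15), a cartilage matrix protein, Ryr2 (-2.90), a calcium release channel, Grin2c (-2.74), a glutamate receptor subunit, Kcnma1 (-2.66), a calcium-activated potassium channel, and Epha3 (-2.64), an ephrin receptor. Their SEs were 0.37 to 0.75 and their limma adjusted p between 0.0019 and 0.0307. Of the estimated reads, Tcap went from 123 to 3.5 in females and from 54.5 to 8 in males, Ryr2 from 74.5 to 11 and from 41 to 7.5, and Grin2c from 100 to 9.5 and from 129 to 22. Cib3 went from 93.5 to 0.5 estimated reads in females and from 33 to 6.5 in males, Thsd7b from 58 to 2.5 and from 25 to 0.5, Cacng5 from 15 to 0.5 and from 43 to 4, and Glra3 from 20 to 1 and from 22.5 to 4.5. Further increases were seen in Ticam2 (2.71), an adaptor of Toll-like receptor 4, Depp1 (2.69), a target of FOXO transcription factors, Kbtbd8 (2.30), Angptl1 (2.04), Ripply3 (2.04) and Aloxe3 (1.99), a lipoxygenase. The SEs of these were 0.39 to 0.66 and the adjusted p between 0.00502 and 0.0456. Ticam2 went from 7.4 to 48.2 estimated reads in females and from 19.5 to 155.7 in males, Ripply3 from 3.5 to 17.5 and from 9 to 45, and Aloxe3 from 6 to 38 and from 3.5 to 12. Fgf20, a growth factor, went from 3 to 19 estimated reads in females and from 0 to 28.5 in males, and Paqr5 from 5.5 to 20 and from 0 to 17.5. Mup22 and Mup11 (2.2 to 621 and 0.7 to 129 estimated reads in females) belong to the major urinary proteins, a family of near-identical genes, and Hspa1b is nearly identical to its neighbour Hspa1a, so how their reads were divided is uncertain.

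Kcnc1 is ENSMUSG00000058975 (mm39 chromosome 7, 46045674 to 46106392), Matn1 is ENSMUSG00000040533 (chromosome 4, 130670216 to 130682787), Cyp1a1 is ENSMUSG00000032315 (chromosome 9, 57595211 to 57611107) and Hspa1b is ENSMUSG00000090877 (chromosome 17, 35175412 to 35178214). In total limma called 1404 of 19367 genes at an adjusted p under 0.05, of which 578 rose and 826 fell. The count was 775 without female static replicate 1, 623 without female static replicate 2, 891 without male static replicate 3, 743 and 692 without female SMG replicates 1 and 2, and 773, 719 and 747 without male SMG replicates 1, 2 and 3. It was 601 without the 3 libraries lowest on the first component (505 shared with the 1404), 217 with adipocyte, macrophage and endothelial scores as covariates (205 shared) and 919 after removal of a trend with gene span (796 shared), all 3 settings added after seeing the data. Sample quality weights gave 7954 by the default estimator, which did not converge, and 5195 by a gene-by-gene one. Cyp1a1, Depp1, Hspa1b, Angptl1, Kcnc1, Matn1, Kcnma1 and Epha3 stayed past the threshold in each of 34 settings.

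**Figure D2:**
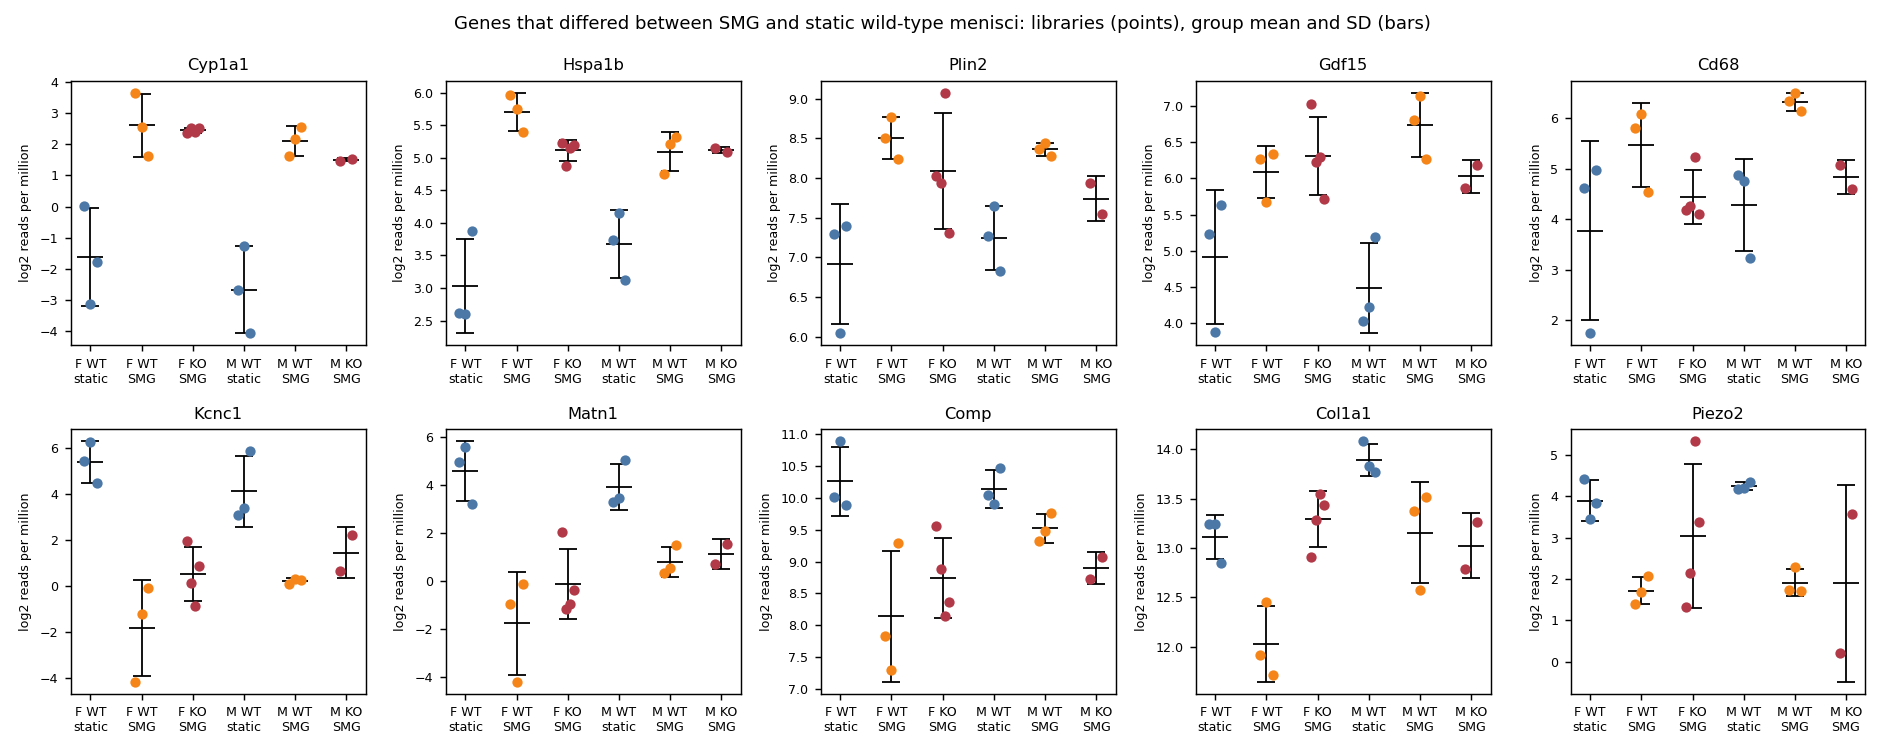
Log2 RPM of 10 genes in the static and SMG wild-type libraries, females and males apart, with points for libraries and bars for the mean ± SD (n = 3). Cyp1a1 and Hspa1b are higher and Kcnc1 and Matn1 lower in every SMG library than in every static library of the same sex.

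A few genes of the matrix lists passed when both sexes were averaged. Of 21 measured cartilage matrix genes, 3 fell over all genes and 3 adjusted over the list alone: Matn1, Comp (-1.37 ± 0.31), which binds collagen fibrils, and Sox5 (-1.10 ± 0.28), a chondrocyte transcription factor. The list's median log2 change was -0.49 and camera called it lower with an adjusted p of 0.00986 (adjusted p = 0.680 with an estimated correlation), but the median was -1.26 in females and 0.32 in males. Of 24 fibrous matrix genes 2 fell, Tnc (-1.02) and Col1a1 (-0.91), and 3 fell adjusted over the list alone. Of 20 hypertrophy and mineralization genes Ibsp (-1.38) fell and Panx3 (1.38) rose, with 2 down and 1 up adjusted over the list alone. The medians of these lists were -0.34 and -0.42 and camera called both lower, with adjusted p of 0.0489 and 0.0240 (both adjusted p = 0.680 with an estimated correlation). In females and males apart they were -0.06 and -0.54 for fibrous matrix and -0.76 and -0.13 for hypertrophy. Among 18 matrix proteases and inhibitors Timp3 fell (-0.77), with 2 lower adjusted over the list alone, and camera did not call the list (median 0.18, adjusted p = 0.726). Of 21 mechanosensing, YAP target and contractile genes 1 fell in either count, Piezo2 (-2.26 ± 0.59), a mechanically gated ion channel, with a list median of -0.21 and a camera adjusted p of 0.0560. Of 19 WNT pathway genes 1 fell in either count, Znrf3 (-0.72), with a camera adjusted p of 0.397. The limma adjusted p of the genes named here lay between 0.00246 and 0.0408. The camera call of cartilage matrix was lost without female SMG replicate 2 (median -0.39). That of fibrous matrix was lost without any 1 of 7 libraries (medians of -0.37 to -0.26): female static replicates 1 and 3, male static replicates 1 and 2, female SMG replicate 1, male SMG replicate 2 or female knockout replicate 1. That of hypertrophy was lost without any 1 of 5 (medians of -0.43 to -0.31): female static replicates 1 and 2, male static replicate 3, female SMG replicate 2 or male SMG replicate 2.

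Camera called 3 lists of lipid and energy metabolism higher. Of 25 genes of fatty acid uptake and oxidation, 22 had positive changes and 2 rose in either count: Angptl4 (1.45 ± 0.37), an inhibitor of lipoprotein lipase, and Plin2 (1.35 ± 0.27), a lipid droplet protein, with limma adjusted p of 0.0279 and 0.0107. Of 21 genes of sterol and fatty acid synthesis Idi1 rose (0.59 ± 0.13), also adjusted over the list alone. None of 21 nuclear-encoded oxidative phosphorylation genes passed limma's adjusted threshold in either count, while 20 had positive changes and the median was 0.34. The camera adjusted p were 0.000331, 0.00464 and 0.000331 for these 3 lists, each adjusted p = 0.680 with an estimated correlation. Without female static replicate 2 the median of fatty acid uptake and oxidation was 0.27 against 0.44, and without male static replicate 3 that of oxidative phosphorylation was 0.20. Cd36, itself a fatty acid receptor, stood at 1.29 ± 0.46 with a limma adjusted p of 0.0944. Neither the 13 mitochondrially encoded genes (median 0.22, camera adjusted p = 0.153) nor the 20 glycolysis and hypoxia genes (median 0.13, camera adjusted p = 0.368) held a called member in either count.

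Among stress and cell cycle genes, 5 of 16 p53 targets and senescence genes rose, led by Gdf15 (1.72 ± 0.30), a secreted stress cytokine, Eda2r (0.87), Phlda3 (0.76) and Aen (0.53), with limma adjusted p from 0.00532 to 0.0418. Adjusted over the list alone, 8 rose and 1 fell, and camera called the list higher (adjusted p of 0.000331, adjusted p = 0.680 with an estimated correlation). The 13 immediate early genes had a median of 0.60 and 1 rose adjusted over the list alone, none over all genes, with a camera adjusted p of 0.00315 (adjusted p = 0.680 with an estimated correlation). Trib3 (0.94) rose and Xbp1 (-0.36) fell among 15 unfolded protein and amino acid stress genes, with 1 up and 3 down adjusted over the list alone and a camera adjusted p of 0.693. Of 20 cell cycle genes Pcna rose (0.37) and none passed adjusted over the list alone, while the list median was -0.47 and its camera adjusted p 0.141. No member of the interferon response (17 measured) or of the inflammatory cytokines and chemokines (18 measured) passed limma's threshold in either count. Their medians were 0.43 and 0.54, with camera adjusted p of 0.0240 (adjusted p = 0.680 with an estimated correlation) and 0.134. The interferon call was lost without female SMG replicate 3 (median 0.15), female static replicate 1 (0.33), female static replicate 2 (0.29) or male static replicate 3 (0.29). The median was 0.84 without female static replicate 3 and 0.68 without female SMG replicate 2.

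Of other cell types, all 12 macrophage markers had positive changes (median 1.40). Of these Cd68 rose in either count (1.87 ± 0.48, limma adjusted p = 0.0293). The 10 endothelial markers had a median of 1.23 and none passed in either count. Camera called both lists higher, with adjusted p of 0.00121 and 0.0310, each with an adjusted p = 0.680 with an estimated correlation. In females and males apart the medians were -0.14 and 2.89 for macrophage and 0.09 and 2.01 for endothelial markers. The macrophage median was 0.84 without female static replicate 2. The endothelial call was lost without any 1 of 5 libraries (medians of 0.77 to 1.16): female static replicates 2 and 3, male static replicate 2 or female SMG replicates 1 and 3. Adipocyte (12 measured, median 0.91), osteoclast (7, -0.12) and nerve and Schwann markers (6, 0.28) were not called, with camera adjusted p of 0.192, 0.726 and 0.706, and of these Mbp (1.03) alone rose adjusted over the list alone. Of skeletal muscle markers 4 were measured and of blood and marrow markers 2, too few for camera, and 2 muscle genes, Neb (-0.89) and Ttn (-0.59), fell adjusted over the list alone but not over all genes. The 9 measured sex chromosome genes held no call in either count (camera adjusted p = 0.965). Of 15 measured neighbours of Cd36 on chromosome 5, Sema3d (-1.72), Pclo (-1.53), Cacna2d1 (-1.24) and Magi2 (-0.78) fell, with 5 down and 1 up adjusted over the list alone, and camera called the list lower with an adjusted p of 0.0121 (adjusted p = 0.680 with an estimated correlation). Magi2 turned to 0.22 when a trend with gene span was removed. Long genes were lower as a class: 53.2% of the 630 coding genes that fell spanned over 100 kb, against 2.1% of the 531 that rose and 14.8% of all coding genes tested. Relative to each gene's mean over the libraries, the median of coding genes over 100 kb minus that of genes under 10 kb was 0.023 to 0.419 in static and -0.305 to -0.064 in SMG wild-type libraries. The 2 conditions were separate with an exact permutation p of 0.005 (two-sided, 400 splits within sex, the smallest they can give).

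**Figure D3:**
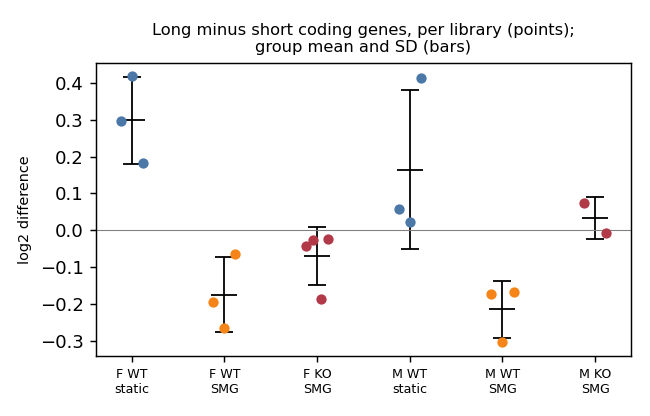
Median log2 RPM, relative to each gene's mean, of coding genes spanning over 100 kb minus that of genes spanning under 10 kb, in each of the 18 libraries by group, with points for libraries and bars for the group mean ± SD. All 6 static libraries lie at 0.023 or above, all 6 wild-type SMG libraries at -0.064 or below, and the 6 knockout libraries between -0.188 and 0.074.

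In wild-type females alone, cartilage genes were among the decreases. Kcnc1 changed by -7.21 ± 0.97 (SE, 3 against 3 libraries), Matn1 by -6.35 ± 0.99, Tcap by -4.93 ± 0.93, Cilp2 by -4.31 ± 0.87 and Comp by -2.13 ± 0.44, while Cib3 kept 0.5 of 93.5 estimated reads. Of 21 cartilage matrix genes, 20 had negative changes (median -1.26), with 2 that fell over all genes and 8 adjusted over the list alone. Without female SMG replicate 2 the median was -0.77. Increases were led by Cyp1a1 (4.24 ± 0.74), Depp1 (2.91 ± 0.65), Hspa1b (2.67 ± 0.31), Rell2 (2.32 ± 0.54, from 4.6 to 29.9 reads) and Gdpd1 (2.23 ± 0.54). All 13 mitochondrially encoded genes had positive changes (median 0.77), 9 of them past the threshold adjusted over the list alone and none over all genes.

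Limma called 353 genes in females, 110 higher and 243 lower, with adjusted p of 0.0121 for Matn1, 0.0293 for Comp and 0.00559 for Hspa1b. Other called list members were Plin2 (1.59), Idi1 (0.82), Nfkbia (-0.75), an inhibitor of NF-kappaB, Xbp1 (-0.54), Sema3d (-2.48) and Cacna2d1 (-1.57), with adjusted p between 0.00791 and 0.0484. Camera called cartilage matrix (6.02e-07), hypertrophy and mineralization (0.000744) and the neighbours of Cd36 (0.00225) lower, the figures being adjusted p. It called fatty acid uptake and oxidation (0.000114), sterol and fatty acid synthesis (0.000355), oxidative phosphorylation (2.79e-07), mitochondrially encoded genes (5.76e-06) and p53 targets (0.0271) higher. Each of these 8 lists had an adjusted p = 0.667 with an estimated correlation. The interferon response was called higher too (median 0.69), at an adjusted p of 0.0271 (adjusted p = 0.931 with an estimated correlation). Female SMG replicate 3 had a mean of 4.95 log2 over this list against 2.77 and 2.38 in the other SMG females. Without it the median was 0.19 and the call was lost (adjusted p of 0.993), as it was without female static replicates 1 (0.51) and 2 (0.35). The median was 1.33 without female static replicate 3 and 1.08 without female SMG replicate 2. The call of p53 targets was lost without female static replicate 2 (median 0.30) and female SMG replicates 1 (0.45) and 3 (0.54). Without female static replicate 2 the median of sterol and fatty acid synthesis was 0.31 against 0.51. No macrophage marker passed in females in either count (median -0.14, camera adjusted p = 0.922). The count of 353 depended on single libraries: it was 7, 0 and 787 without female static replicates 1, 2 and 3, and 4 and 4 without female SMG replicates 1 and 2. Among libraries outside these groups it was 222 and 928 without male static replicates 1 and 3, 166, 196 and 175 without male SMG replicates 1, 2 and 3, and 218, 626 and 231 without female knockout replicates 1, 2 and 4. It was 97 without the 3 libraries lowest on the first component, 854 with the cell type scores as covariates, 113 without the span trend, 188 with voom weights and 41 with only the 2 groups in the fit. Sample quality weights gave 8312 and 5143 by the 2 estimators, and the replicate block 6.

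In wild-type males, the largest increases included immune cell genes. Cd5l, a protein secreted by macrophages, changed by 7.16 ± 1.13 (SE, 3 against 3 libraries), from 14 to 1802 estimated reads. Bin2 changed by 3.87 ± 0.80, from 5 to 95.5 reads, and Slamf7, a receptor of immune cells, by 3.70 ± 0.69, beside Cyp1a1 at 4.79 ± 0.74 and Fgf20, which went from 0 to 28.5 reads. All 12 macrophage markers had positive changes (median 2.89), each past the threshold adjusted over the list alone and none over all genes. All 10 endothelial markers had positive changes (median 2.01), none past in either count. Decreases were led by Myo5c (-2.38 ± 0.49), Cemip (-2.08 ± 0.36), a protein needed for hyaluronan breakdown, Pcsk5 (-1.96 ± 0.41), Meg3 (-1.56 ± 0.33) and Cacnb2 (-1.55 ± 0.30). Of 21 cartilage matrix genes none passed in either count in males and the median was 0.32.

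Limma called 98 genes in males, 62 higher and 36 lower, with adjusted p of 0.0182 for Cd5l and 0.015 for Cyp1a1. Called list members were Gdf15 (2.26 ± 0.43), Sesn2 (0.66 ± 0.13) and Egr2 (1.71 ± 0.34), at adjusted p of 0.0324, 0.0360 and 0.0395, and 5 p53 targets and 6 immediate early genes rose adjusted over the list alone. Camera called macrophage markers (adjusted p of 1.95e-08) and p53 targets (9.62e-05) higher, each adjusted p = 0.586 with an estimated correlation, and immediate early genes (1.12e-06) higher, adjusted p = 0.588 with an estimated correlation. It called endothelial markers (0.00125), inflammatory cytokines and chemokines (0.0102) and fatty acid uptake and oxidation (0.0209) higher, and fibrous matrix (0.0102), mitochondrially encoded (0.0102) and cell cycle genes (0.0235) lower, each adjusted p = 0.838 with an estimated correlation. The call of endothelial markers was lost without male static replicate 2 (median 1.25) and that of inflammatory genes without male static replicate 3 (0.27 against 0.56). The inflammatory median was 0.94 and 0.97 without male static replicates 1 and 2 and 1.08 without male SMG replicate 2. The call of fatty acid uptake was lost without male static replicate 3 (0.13) and male SMG replicate 2 (0.29), and that of mitochondrially encoded genes without male static replicate 1 (-0.16) and male SMG replicate 3 (-0.38). Fibrous matrix lost its call without male static replicates 1 (-0.37) and 2 (-0.31) and male SMG replicate 2 (-0.38). The cell cycle lost it without male static replicates 1 (-0.23) and 2 (-0.54) and male SMG replicate 3 (-0.36), and stood at -1.40 without male static replicate 3. The count of 98 was 8 and 10 without male static replicates 1 and 2, and 5, 6 and 7 without male SMG replicates 1, 2 and 3. Among libraries outside these groups it was 48 and 177 without female static replicates 1 and 2, 62 and 160 without female SMG replicates 2 and 3, 59 and 59 without male knockout replicates 1 and 3, and 173 and 43 without female knockout replicates 2 and 4. It was 223 without the 3 libraries lowest on the first component, 2 with the cell type scores as covariates, 23 without the span trend and 423 with a pseudocount of 10. With sample quality weights it was 6343 and 4004 by the 2 estimators, and 1 with the replicate block.

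**Figure D4:**
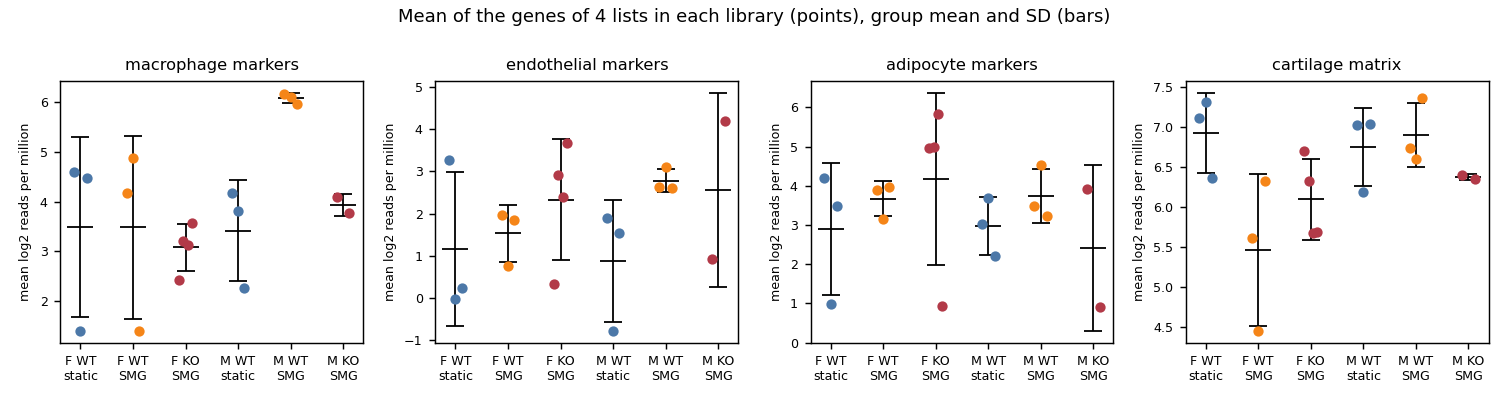
Mean log2 RPM of the macrophage, endothelial, adipocyte and cartilage matrix lists in each of the 18 libraries by group, with bars for the group mean ± SD. The 3 male wild-type SMG libraries have macrophage means of 5.97 to 6.17, above the other 15 libraries at 1.40 to 4.89.

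Whether SMG acted differently in the sexes was tested as the difference of the effects. No single gene passed: limma called 0 genes, with 1419 at an unadjusted p under 0.05 and a smallest adjusted p of 0.469. As sets, all 21 cartilage matrix genes had a lower change in females than in males (median difference -1.63 log2), and so had all 12 macrophage markers (median -3.04), while all 13 mitochondrially encoded genes (1.20) and all 21 oxidative phosphorylation genes (0.50) had positive differences. The medians were -1.04 for cartilage matrix without female SMG replicate 2 and -1.90 for macrophage markers without female SMG replicate 3. For oxidative phosphorylation they were 0.32 without female static replicate 2 and 0.76 without male static replicate 3. Of these genes, 6 mitochondrially encoded ones passed adjusted over the list alone and none of the others did.

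Camera called 11 lists for this difference, with adjusted p of 2.39e-09 for cartilage matrix, 5.35e-07 for macrophage markers and 2.58e-11 for mitochondrially encoded genes, each adjusted p = 0.575 with an estimated correlation, and of 3.75e-06 for oxidative phosphorylation, adjusted p = 0.686 with an estimated correlation. Between the female and the male effect, 24 genes were called in both, all with the same sign, 334 of the 353 female calls (94.6%) had the same sign in males and 88 of the 98 male calls (89.8%) the same sign in females. Across genes, which are not independent replicates, the 2 effects correlated with r = 0.351. A pseudocount of 10 gave 12 called genes and the cell type covariates gave 1. With sample quality weights the count was 6882 by the default estimator, which did not converge, and 3687 by the gene-by-gene one.

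Knockout and wild type were compared under SMG to ask how CD36 affects the cultured tissue. Few genes differed in both sexes averaged. Beside Cd36, Abhd1, a hydrolase-domain protein, was higher by 3.66 ± 0.35 log2 (SE, 6 against 6 libraries) and Dnm1l, the GTPase that divides mitochondria, by 0.98 ± 0.08, while Wdfy1, an endosomal adaptor protein, was lower by 1.19 on the log2 scale (-1.19 ± 0.13). A pair of long noncoding RNAs completed the calls, AI506816 (-5.02 ± 0.24) and Gm56714 (2.12 ± 0.29), which fall outside the naming rule and were chosen after their values were seen. All of these except Cd36 (5 genes) separated the 6 knockout libraries from all 12 wild-type libraries, static ones included. A random order of the libraries does this for 0.0108% of genes, but these genes were called on the same libraries, so their separation is in part built in.

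Limma called 6 genes, 3 higher and 3 lower, with 1424 at an unadjusted p under 0.05. The adjusted p was 2.38e-08 for AI506816, 9.01e-06 for Dnm1l, 0.000126 for Abhd1, 0.000454 for Wdfy1 and 0.00784 for Gm56714. Of the called genes 3 lie on chromosome 5 with Cd36: Abhd1 (ENSMUSG00000006638, 31107410 to 31112435) is 13.1 Mb and AI506816 (ENSMUSG00000105987, 23903290 to 23917684) 5.9 Mb away. Dnm1l (ENSMUSG00000022789) is on chromosome 16 at 16128677 to 16176904, Wdfy1 (ENSMUSG00000073643) on chromosome 1 at 79679017 to 79753860 and Gm56714 (ENSMUSG00000120284) on chromosome 15 at 33221526 to 33223217. The count was 10 without female wild-type SMG replicate 3 and 20 with a pseudocount of 10. Sample quality weights gave 21 by the default estimator and 19 by the gene-by-gene one, and knockout against wild type cannot be compared in static culture here.

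**Figure D5:**
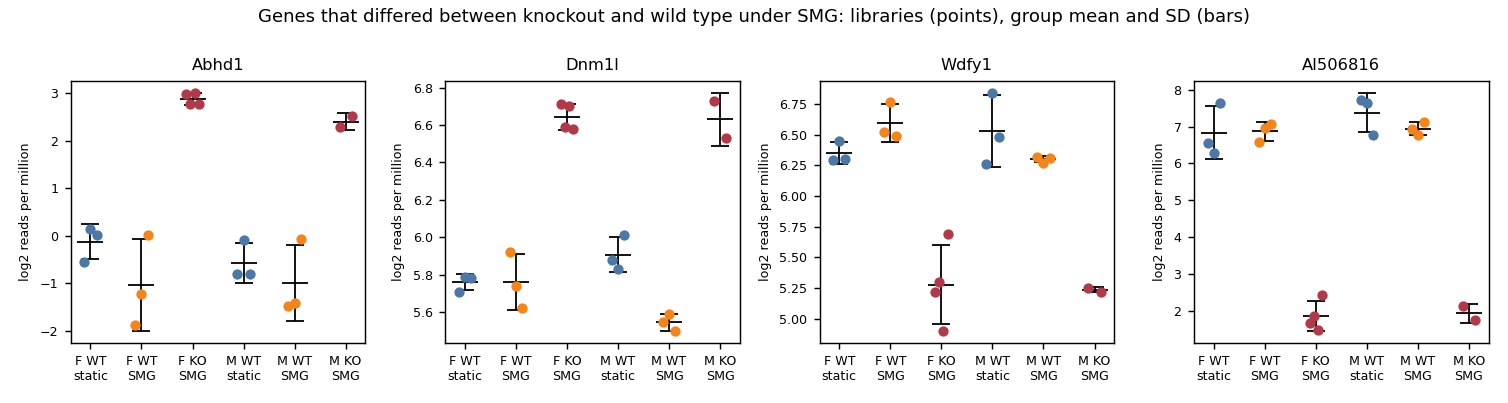
Log2 RPM of Abhd1, Dnm1l, Wdfy1 and AI506816 in each of the 18 libraries by group, with bars for the group mean ± SD. The 6 knockout libraries lie apart from the 12 wild-type libraries for each gene, as for AI506816 with 1.48 to 2.41 against 6.28 to 7.73.

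No member of any list passed over all genes in the knockout comparison, and of the interferon genes Rsad2 (-2.81 ± 0.64) alone fell adjusted over the list alone, with a limma adjusted p of 0.485 over all genes. All 12 macrophage markers had negative differences (median -1.38). In females the median was -0.35 (camera adjusted p = 0.257), the knockout libraries having list means of 2.43 to 3.56 log2 within the 1.40 to 4.89 of wild-type SMG. In males it was -2.31, with 4.09 and 3.78 in the knockout against 5.97 to 6.17 in the wild-type SMG libraries, which stood above all others. Differences were negative in 16 of 17 interferon genes (median -1.06), 16 of 18 matrix proteases and inhibitors (-0.61) and 14 of 18 inflammatory cytokines and chemokines (-0.61). Differences were also negative in 11 of 13 immediate early genes (-0.45), 18 of 20 cell cycle genes (-0.33) and 20 of 21 oxidative phosphorylation genes (-0.22), and 17 of 20 hypertrophy and mineralization genes had positive ones (0.31). Camera called the macrophage (adjusted p of 3.53e-05), interferon (4.73e-05), protease (0.00311), inflammatory (0.00311) and immediate early lists (0.00150) lower, each adjusted p = 0.807 with an estimated correlation. It called oxidative phosphorylation (0.00113) and the cell cycle (0.00432) lower, each adjusted p = 0.909 with an estimated correlation, and hypertrophy and mineralization (0.0396) higher, adjusted p = 0.909 with an estimated correlation. Of the interferon list, wild-type female SMG replicate 3 had a mean of 4.95 log2, against 1.74 to 2.91 in the other 11 SMG libraries of either genotype. Without this library the median was -0.43 (camera adjusted p of 0.0249). The inflammatory call was lost without male knockout replicate 3 (median -0.34), and the median was -1.04 without male knockout replicate 1. The immediate early call was lost without male knockout replicate 3 (-0.29), and the median was -0.29 without female knockout replicate 3. The hypertrophy call was lost without any 1 of 5 libraries (medians of 0.14 to 0.28): female wild-type SMG replicate 2, male wild-type SMG replicate 2, female knockout replicates 1 and 3 or male knockout replicate 3. Its median was 0.48 without female knockout replicate 2. The 25 genes of fatty acid uptake and oxidation were not called (median -0.20, camera adjusted p = 0.115), and neither was cartilage matrix (median 0.10, camera adjusted p = 0.782).

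Within females, 4 knockout libraries against 3 gave the calls Abhd1 (3.91 ± 0.44), Dnm1l (0.89 ± 0.10), Wdfy1 (-1.32 ± 0.16) and AI506816 (-5.02 ± 0.31), and Cd36 itself differed by -2.87 ± 0.61 without passing. In males, 2 knockout libraries against 3 gave Dnm1l (1.08 ± 0.12) and AI506816 (-5.02 ± 0.37), and Cd36 differed by -4.18 ± 0.72 without passing. Cartilage matrix genes had positive differences in 20 of 21 cases in females (median 0.63) and negative ones in 17 of 21 in males (median -0.43). Immediate early genes had positive ones in 11 of 13 in females (median 0.30) and negative ones in 13 of 13 in males (median -1.10), of which 6 fell adjusted over the list alone.

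Limma called these 4 genes in females, with adjusted p from 9.22e-07 to 0.00309, and 2 in males, with 0.000893 and 1.22e-05. The adjusted p of Cd36 was 0.289 in females and 0.162 in males. The difference of the knockout effect between the sexes held 0 genes by limma, with 1185 at an unadjusted p under 0.05, and 1 without female wild-type SMG replicate 3. The immediate early list differed, with a median of 1.38 and 7 members adjusted over the list alone (camera adjusted p of 2.24e-10, adjusted p = 0.332 with an estimated correlation), as did cartilage matrix, with a median of 1.27 (adjusted p of 0.000190, adjusted p = 0.668 with an estimated correlation). Without female wild-type SMG replicate 2 the cartilage median of this difference was 0.68. The male count was 1 without male knockout replicate 1, 4 without male knockout replicate 3, 4 without female wild-type SMG replicate 3 and 4 without female knockout replicate 3, and 53 with a pseudocount of 10. The male group of 2 leaves the spread to the other groups, and with only the groups compared in the fit the counts were 1 in females and 118 in males. Sample quality weights gave 57 and 54 in females and 10 and 10 in males by the 2 estimators, and 1 by the default one for the difference. The cell type covariates gave 12 in females and 1 for the difference, which was 3 with the sex of the library names.

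Camera called 8 lists in each sex for the knockout. In females cartilage matrix (adjusted p of 0.00108), hypertrophy and mineralization (median 0.72, 7.65e-05) and immediate early genes (0.0361) were called higher. Interferon (median -1.10, 9.05e-06), cell cycle (-0.73, 9.05e-06), oxidative phosphorylation (-0.20, 0.00162), protease (-0.48, 0.0361) and mitochondrially encoded genes (-0.21, 0.0361) were called lower, the second number in each bracket being the adjusted p. Each of these 8 had an adjusted p = 0.801 with an estimated correlation. In males all 8 were called lower: fibrous matrix (median -0.43, 0.0444), proteases (-0.49, 0.0426), fatty acid uptake and oxidation (-0.25, 0.0362) and glycolysis and hypoxia (-0.28, 0.0362), each adjusted p = 0.783 with an estimated correlation, and inflammatory (-1.15, 0.000461) and macrophage genes (-2.31, 1.89e-06), each adjusted p = 0.50 with an estimated correlation. The others were unfolded protein and amino acid stress (-0.34, 2.29e-05, adjusted p = 0.205 with an estimated correlation) and immediate early genes (-1.10, 2.03e-09, adjusted p = 0.413 with an estimated correlation).

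Single libraries decided several of these calls. In females the interferon call was lost without wild-type SMG replicate 3 (median -0.15, against -1.71 without replicate 2) and the cartilage call without wild-type SMG replicate 2 (0.18 against 0.63, and 1.17 without replicate 3). The immediate early median was -0.03, with the direction of the test reversed, without knockout replicate 2, whose mean of 7.23 log2 over the list compared with 4.87 to 6.27 in the other knockout females. It was 0.63 without knockout replicate 3, and the call was lost without knockout replicate 4 (0.19), wild-type SMG replicates 2 (0.25) and 3 (0.40) and male static replicate 3 (0.30). Oxidative phosphorylation lost its call without knockout replicate 3 (-0.09) and wild-type SMG replicate 2 (-0.11), with -0.38 without knockout replicate 2 and -0.30 without wild-type SMG replicate 1. Mitochondrially encoded genes lost it without knockout replicates 1 (-0.10) and 3 (-0.01) and wild-type SMG replicate 3 (-0.20), with -0.44 and -0.36 without knockout replicates 2 and 4. Proteases lost it without any 1 of 5 libraries (-0.58 to -0.41), knockout replicates 1, 3 and 4 or wild-type SMG replicates 2 and 3, with -0.91 without knockout replicate 2. The medians without 1 library were 1.13 for hypertrophy (knockout replicate 2) and -0.46 for the cell cycle (knockout replicate 3).

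In males the inflammatory call was lost without knockout replicate 3 (median -0.31). Proteases lost it without knockout replicate 3 (-0.18) and wild-type SMG replicates 1 (-0.45) and 3 (-0.49). Fatty acid uptake lost it without knockout replicate 3 (-0.21) and wild-type SMG replicate 2 (-0.21), with -0.37 without knockout replicate 1. Fibrous matrix and glycolysis lost it without knockout replicate 1 (-0.27 and -0.26) and wild-type SMG replicates 1 (-0.42 and -0.25) and 3 (-0.36 and -0.14).

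Females and males differed only in sex chromosome genes among those called. In static wild type, SMG wild type and SMG knockout alike, Xist was higher in females and Ddx3y, Uty, Eif2s3y, Kdm5d, Gm29650 and Gm4017, all on the Y chromosome, were lower, near 0 reads in females. Limma called these 7 genes in each of the 3 conditions, the last 2 chosen after their values were seen. The Xist difference was 12.37 ± 0.36 log2 (SE) in static wild type, 11.33 ± 0.36 in SMG wild type and 12.45 ± 0.38 in SMG knockout, with adjusted p of 9.79e-12, 1.85e-11 and 1.47e-11.

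No other gene passed in these comparisons, though 1179, 1737 and 397 genes had an unadjusted p under 0.05. Under SMG all 12 macrophage markers had negative differences between wild-type females and males (median -2.95), 10 of them past the threshold adjusted over the list alone, and so had all 21 cartilage matrix genes (median -1.42), 6 of them past it. Camera called both lower in females, with adjusted p of 4.51e-10 and 6.81e-12, each adjusted p = 0.194 with an estimated correlation. Without female SMG replicate 3 the macrophage median was -1.64. Camera called 6 lists in static wild type, 13 in SMG wild type and 12 in the knockout, none of which passed with an estimated correlation (adjusted p = 0.079 to 0.904). Leaving out 1 library ended the call of 17 of these 31 lists, as of adipocyte markers in the knockout (median 1.87, and 0.16 without male knockout replicate 3). In the static comparison 94 genes were called without male static replicate 3, and under SMG 112 with a pseudocount of 10. Sample quality weights gave 12543 and 6238 in static and 452 and 500 in SMG wild type by the 2 estimators. Without the 3 libraries lowest on the first component the count was 12 in both, and under SMG it was 33 with only the groups compared and 27 with the cell type covariates. With the sex of the library names limma called 0 in each condition, with 1146, 1719 and 345 at an unadjusted p under 0.05. Quantile normalization called 8 genes in static and 10 in SMG wild type, with 25% and 40% of them higher in females against 14.3% on the deposited scale.

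The changes under SMG and those of the knockout were compared for opposite directions. Of the 1404 genes called between SMG and static, 1147 (81.7%) had the opposite sign in the knockout comparison, and 0 genes were called by limma in both, where independent lists of these sizes would share 0.0895 and 0.128 by chance in the opposite directions. The 0 was 13 with a pseudocount of 10, 13 and 12 with sample quality weights by the default and the gene-by-gene estimator, and 4 without female wild-type SMG replicate 3. Both comparisons use the wild-type SMG libraries, one adding and one subtracting them, so opposite signs arise without any effect. Across genes r was -0.543 and the covariance -0.153, while unchanged groups simulated against these libraries gave a mean r of -0.496 (-0.825 to 0.112 over 100 draws) and a mean covariance of -0.074 (-0.221 to 0.022), a difference in covariance of -0.079 that lies within the spread of the draws. With the wild-type SMG libraries split so that each comparison had its own, r was -0.326 on average (-0.396 to -0.211 over 18 splits), with each split leaving few libraries per group. The covariance over these splits was -0.11 on average (-0.132 to -0.072). In the 100 draws of unchanged groups the average covariance had a mean of -0.001 (-0.165 to 0.101). They were split alike after the observed splits had been seen, and 2 draws were as low as the observed one. In all these draws SMG had no effect either. The spread expected with an SMG effect but no knockout effect was not tested.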

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

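The tests on the knockout differences near Cd36, on the knockout libraries' long genes, on the share of the main cell type and on the male macrophage score were chosen only after their results were seen.

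Among the 4 female knockout libraries, 4 of 35 measures had a library far from the others by Dixon's 95% limit on the gap over the range, and chance marks about 1 in 20 groups. The span index, the level of coding genes over 100 kb relative to genes under 10 kb, was -0.188 in replicate 2 against -0.042 to -0.025 in the others. The mean of the fibrous matrix list was 9.11 log2 in replicate 2 against 7.68 to 7.82. Cd36 stood at 3.82 log2 in replicate 3 against 5.93 to 6.27, and the mean of the osteoclast markers at 2.28 in replicate 3 against 3.23 to 3.36.

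The SMG effect differed between the sexes in 11 lists by a test of the difference itself (camera at its preset correlation). The median difference, females minus males, was -1.63 log2 for cartilage matrix, -0.87 for hypertrophy and mineralization, -0.55 for inflammatory cytokines and chemokines, 0.38 for sterol and fatty acid synthesis, 0.50 for nuclear-encoded oxidative phosphorylation and 1.20 for mitochondrially encoded genes. It was -0.27 for unfolded protein and amino acid stress, -0.80 for immediate early genes, -3.04 for macrophage markers, -1.61 for endothelial markers and -0.32 for the neighbours of Cd36. Leaving out 1 library ended the call of inflammatory genes in 8 cases (medians of -0.69 to 0.17), unfolded protein stress in 9 (-0.27 to -0.13), the neighbours of Cd36 in 11 (-0.44 to -0.23), sterol synthesis in 4 (0.23 to 0.29; female static replicate 2, male static replicate 2, female SMG replicate 2 or male SMG replicate 1) and endothelial markers in 3 (-1.16 to -0.71; female static replicate 1, male static replicate 2 or female SMG replicate 2). The median of calls that held moved to -1.02 and -0.93 for inflammatory genes without female and male static replicate 2, to -0.53 for the neighbours of Cd36 without male static replicate 3, to -1.04 for cartilage matrix without female SMG replicate 2 and to -1.90 for macrophage markers without female SMG replicate 3. For oxidative phosphorylation it moved to 0.32 without female static replicate 2 and to 0.76 without male static replicate 3. The camera adjusted p lay between 2.58e-11 and 0.0476, and between 0.575 and 0.688 with an estimated correlation. For the number of these lists chance could not be excluded: 21 of 100 splits called as many, with 11 in the real split and up to 16 in another. No gene was called by limma for this difference (0, with 1419 at an unadjusted p under 0.05). With 0 in the real split the 100 splits decide nothing about this count, but another split called 966, which points to a structure of the samples that crosses the groups.

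The knockout effect differed between the sexes in 11 lists by the same test, with 2 male knockout libraries. The median difference, females minus males, was 1.27 log2 for cartilage matrix, 0.52 for fibrous matrix, 0.79 for hypertrophy and mineralization, 0.22 for inflammatory cytokines and chemokines, 0.40 for glycolysis and hypoxia and -0.41 for mitochondrially encoded genes. It was -0.67 for the cell cycle, 0.47 for unfolded protein and amino acid stress, 1.38 for immediate early genes, 2.30 for adipocyte markers and 1.72 for macrophage markers. Leaving out 1 library ended the call of fibrous matrix in 5 cases (medians of 0.24 to 0.56), adipocyte markers in 6 (0.34 to 1.93), inflammatory genes in 4 (-0.33 to 0.20), mitochondrially encoded genes in 4 (-0.32 to -0.17) and the cell cycle in 3 (-0.55 to -0.45). It ended that of hypertrophy in 2 (0.46 and 0.50), and those of glycolysis (0.32) and macrophage markers (0.76, without female wild-type SMG replicate 3) in 1 each. The median of calls that held moved, without male knockout replicate 1, to 1.18 for inflammatory genes, 3.92 for adipocyte markers, 0.34 for hypertrophy and 0.27 for glycolysis. The inflammatory median was also 0.83 without female knockout replicate 3, 0.81 without male wild-type SMG replicate 2, and 0.39, 0.36 and 0.38 without female wild-type SMG replicates 1, 2 and 3. Without female wild-type SMG replicate 2 the median was 2.67 for macrophage markers and 0.68 for cartilage matrix. The camera adjusted p lay between 2.24e-10 and 0.0319, and between 0.105 and 0.668 with an estimated correlation.

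Genes with a long span were lower under SMG in wild type, the span index differing by -0.428 ± 0.08 (SE, 6 against 6 libraries). A loss of RNA integrity acting on transcript length is not decided. Across coding genes the rank correlation of the change was -0.241 with exon length and -0.283 with the span. The partial rank correlation with exon length, given the span, was -0.068, weaker than that with the span given exon length, -0.167. The span was thus the closer correlate, but no RNA quality value was used to test integrity itself. Loss of a minor cell type that expresses long genes is argued against as the whole cause, because coding genes with a mean of at least 30 RPM showed a difference of -0.408 ± 0.111 (exact permutation p of 0.005, two-sided). An effect of SMG on long genes stays open as a hypothesis, which the knockout SMG libraries do not decide: 5 of 6 lay below every static library over all coding genes, but 1 of 6 over the abundant ones (-0.298 to 0.13, lowest static library -0.131), where 5 of 6 wild-type SMG libraries did. It cannot be told apart from a batch of culture, which the labels do not give.

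Genes near Cd36 on chromosome 5 were over-represented among the knockout differences. Within 20 Mb, 5 of 301 genes had an unadjusted p under 0.001, against 21 of 19065 elsewhere. Fisher's exact test gave an odds ratio of 15.3 (two-sided p = 4.42e-05), and 10.7 (0.00395) without called genes (3 of 299 against 18 of 19062). The 5 were Abhd1, 6030443J06Rik (1.58, 4.8 Mb away) and, close together at 5.9 to 6.1 Mb, AI506816, Rint1 (-0.45) and Hycc1 (-1.62). The test takes genes as independent, so both p may be too low. DNA of another mouse strain around the targeted gene may explain the excess. For the 3 called genes on other chromosomes (Dnm1l, Wdfy1 and Gm56714) such linkage is argued against, while other strain differences elsewhere in the genome were not tested. That 5 called genes separated all knockout from all 12 wild-type libraries decides nothing, since their call in part builds this in and a strain difference would do the same. A response to the loss of CD36 stays open. The knockout's strain is not given in the sources, so the explanations cannot be told apart.

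Macrophage markers were higher in the 3 male wild-type SMG libraries, with means of 5.97 to 6.17 log2 against 1.40 to 4.89 in the other 15. More macrophages in these samples may account for it: of a second list of 17 markers, none of them on the first, 16 had positive changes in males with a median of 2.61, though limma called 0 over all genes and 11 adjusted over the list alone, and Lgals3 (0.76) and Ctss (3.04) were its most abundant members. A lower share of the main cell type is argued against, because the macrophage score rose by 2.14 ± 0.52 log2 more than the mean of the adipocyte, osteoclast and nerve lists, although the endothelial list, which was not among these 3, had a median of 2.01. A response of males to SMG stays open: the exact permutation p of 0.1 (two-sided) is the smallest that 3 against 3 allows and decides nothing, while all 12 markers of the first list passed limma's test in males adjusted over the list alone, none over all genes, and its camera call had an adjusted p = 0.586 with an estimated correlation. A batch of culture, which the labels do not give, and a change of expression within macrophages were not tested.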

How the results depend on the processing

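The settings with voom weights, gene-by-gene sample weights, cell type covariates, removal of the span trend and without the 3 libraries lowest on the first component were chosen after seeing the data, and all other settings before.

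Over all settings, named genes kept their direction and side of the threshold in 20531 cases, lost it in 676, gained it in 486 and turned in 8, and called lists kept it in 3246, lost it in 450 and turned in 26. A list turns where the direction of camera's test against other genes changes: the median changed sign in all but 1 of the 26, and in 12 further cases the median changed sign and the test's direction did not. Counts of calls stayed within 1.5 times in 338 cases and moved in 102. The counts of genes stayed within 1.5 times in all comparisons with a pseudocount of 0.1, no filter, a stricter filter, median-of-ratios scaling, quantile normalization and robust eBayes. Genes near the floor are limited by depth. Except where a cause is given below, the cause was not tested.

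Leaving out 1 library at a time gave 623 to 2078 genes for SMG averaged over sex, 0 (limma, 2320 at an unadjusted p under 0.05) to 928 in females, 5 to 177 in males and 0 in all 18 cases for the difference between the sexes (892 to 3288 at an unadjusted p under 0.05). It gave 5 to 10 for the knockout averaged over sex, 4 to 6 in females, 1 to 4 in males and 0 to 1 for their difference (847 to 1543 at an unadjusted p under 0.05 in the 17 cases with 0). For females against males it gave 7 to 94 in static wild type, 7 to 10 under SMG and 6 to 7 in the knockout. Genes called oppositely by SMG and knockout numbered 0 to 4, and called lists 94 to 113. Without female SMG replicate 3 the interferon list turned in SMG females by its test (adjusted p of 0.993) while its median stayed positive (0.189, up to 1.331 without another library). It turned in females against males under SMG (-0.025, up to 1.011). Without female knockout replicate 2 the immediate early list turned in the female knockout comparison (-0.026, up to 0.627) and oxidative phosphorylation in females against males of the knockout (-0.049, up to 0.241). Where 1 male knockout library is left, it is assumed to vary like the other groups.

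With a pseudocount of 10, which damps the noise of genes with few reads, counts were 423 for SMG in males, 12 for the difference of the SMG effect, 20 for the knockout averaged over sex, 53 for the knockout in males, 112 for sex under SMG and 13 for opposite directions. With only the groups compared in the fit, and so fewer samples, they were 41 for SMG in females, 1 and 118 for the knockout in females and males, and 33 for sex under SMG. Voom weights gave 188 for SMG in females.

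Sample quality weights, whose default estimator did not converge, gave 7954, 8312, 6343 and 6882 genes for SMG averaged over sex, in females, in males and for their difference, 21, 57, 10 and 1 for the knockout in the same order, 12543 and 452 for sex in static and SMG wild type and 13 for opposite directions, and the endothelial list turned for SMG averaged over sex (-0.465). The gene-by-gene estimator gave 5195, 5143, 4004 and 3687 for SMG, 19, 54 and 10 for the knockout averaged over sex, in females and in males, 6238 and 500 for sex and 12 for opposite directions.

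Without the 3 libraries lowest on the first component, counts were 601, 97 and 223 for SMG averaged over sex, in females and in males, and 12 for sex in both static and SMG wild type. With cell type scores as covariates they were 217, 854, 2 and 1 for SMG averaged over sex, in females, in males and for their difference, 12 for the knockout in females, 1 for the difference of the knockout effect and 27 for sex under SMG. The covariates turned the endothelial list for SMG averaged over sex (-0.048) and in males (-0.1), hypertrophy for the knockout averaged over sex (-0.014), proteases (0.274), fatty acid oxidation (0.094) and macrophage markers (0.019) for the knockout in males, macrophage markers for the difference of the knockout effect (-0.106) and adipocyte markers for sex in the knockout (-0.149). The endothelial, macrophage and adipocyte lists are themselves covariates there. Removal of the span trend gave 919, 113 and 23 for SMG averaged over sex, in females and in males, and turned Magi2 to 0.219.

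With the sex of the library names, 5 knockout libraries change sex. Counts were then 3 for the difference of the knockout effect and 0 by limma for sex in static wild type, SMG wild type and knockout (1146, 1719 and 345 at an unadjusted p under 0.05), since mixed sexes raise the spread of sex chromosome genes. Their differences in the knockout turned: Xist -8.153, Ddx3y 8.087, Uty 7.111, Eif2s3y 6.804, Kdm5d 6.475, Gm29650 3.788 and Gm4017 2.551. List medians turned for sex in the knockout: sex chromosome genes -0.169, cartilage matrix 0.65, fatty acid oxidation -0.19, oxidative phosphorylation -0.036, cell cycle 0.165, mechanosensing -0.181, immediate early -0.537, adipocyte -0.443 and macrophage 0.136. So did immediate early genes in the female knockout comparison (-0.305), fatty acid oxidation in the male one (0.005), and the cell cycle (0.094) and adipocyte lists (-0.147) in their difference.

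The replicate numbers, which the titles call donors, were not taken to pair the samples, since each library stands for 1 mouse per the labels. Of 16 pairs with the same number, 4 correlated above 0.1 (range -0.545 to 0.303), and 7 of 17 samples correlated best with their own number. The female static and SMG libraries that share 5 or 6 in the library name correlated with 0.016 and 0.248. With the replicate number as a block, counts were 507 for SMG averaged over sex (500 shared with the 1404), 6 in females and 1 in males, and 3, 1 and 1 for the knockout averaged over sex, in females and in males. Sex could not be compared with the block, which is nested in it.

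With an estimated correlation 0 of the 107 list calls by camera remained, and of 264 list tests 16 had an unadjusted p under 0.05.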

Other observations

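The second macrophage list, which holds Trem2, was chosen after the first list's result was seen, and the heat shock, NRF2 and aryl hydrocarbon receptor lists after Hspa1b, Nqo1 and Cyp1a1 had been seen to rise, all before the values of the other members were looked at (Trem2 excepted).

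Stress response genes not described above were higher under SMG in wild type, averaged over sex. Nqo1, a quinone reductase, rose by 1.86 ± 0.22 log2 (SE, 6 against 6 libraries) and Hspa1a, the near-identical neighbour of Hspa1b, by 1.63 ± 0.20, with limma adjusted p of 0.000638 and 0.000865, both named after their values were seen. Of 20 measured targets of NRF2, the transcription factor of the oxidative stress response, 17 had positive changes (median 0.58) and 6 rose by limma: Cbr3 (1.16), Blvrb (0.95), Srxn1 (0.88), Taldo1 (0.86), Gstm1 (0.82) and Slc7a11 (0.70), the cystine transporter. Of 17 heat shock proteins other than Hspa1a and Hspa1b, 16 had positive changes (median 0.35) and 2 rose, Hspb1 (1.30) and Chordc1 (0.27). Of 8 targets of the aryl hydrocarbon receptor other than Cyp1a1 and Nqo1, 7 had positive changes (median 0.79), 2 rose, Aldh3a1 (1.17) and Nfe2l2 (0.43), the gene of NRF2 itself, and Tiparp fell (-0.98). The limma adjusted p of these members lay between 0.00201 and 0.0494. In females and males apart the medians were 0.57 and 0.55 for NRF2 targets, 0.54 and 0.21 for heat shock proteins and 0.71 and 0.44 for the receptor's targets. Between knockout and wild type under SMG no member was called by limma and the medians were -0.30, -0.25 and -0.38. Camera at its preset correlation called the 3 lists lower in the knockout, with adjusted p of 2.12e-05, 0.00258 and 0.0406 (adjusted p = 0.232, 0.289 and 0.232 with an estimated correlation). The knockout comparison subtracts the wild-type SMG libraries in which these responses were first seen, so lower values arise there without any effect of the knockout. In 100 draws of unchanged groups the SMG and knockout medians had opposite signs in 61, 66 and 58 draws for the 3 lists, and the knockout medians reached -0.41, -0.37 and -0.55.

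As hypotheses, an oxidative stress response (median 0.58), a heat shock response (0.35) and an aryl hydrocarbon receptor response (0.79) may each be part of the SMG effect. The lists were higher than other genes by camera at its preset correlation, with adjusted p of 2.19e-07, 3.27e-06 and 0.0207, and adjusted p = 0.171 for each with an estimated correlation. The second macrophage list had a median of 1.17 averaged over sex with 0 members called by limma (camera adjusted p of 0.000562, adjusted p = 0.230 with an estimated correlation).

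Other splits of the same libraries were counted for each comparison of at least 3 against 3. For SMG averaged over sex chance can be excluded for the genes, since 1 of 100 splits (the real one) gave as many, with 1404 genes in the real split and up to 180 in another. It cannot be excluded for the number of lists, as 8 of 100 splits called as many (12 in the real split, up to 15 in another). For the knockout averaged over sex 2 of 100 splits, a share under 0.05, called as many genes (6). The one beside the real split exchanged only female wild-type SMG replicate 3 and knockout replicate 2, so chance is argued against. It is not excluded for the lists, where 57 of 100 splits called as many (8 against up to 13). For the knockout in females it can be excluded for the genes, with 1 of 35 splits (4 genes against up to 1), and not for the lists, with 26 of 35 (8 against up to 15).

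For comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. SMG in females gave 353 genes and up to 1 in another split, and 9 lists against up to 12, with 8 splits calling as many lists. SMG in males gave 98 genes against up to 0 and 9 lists against up to 11, with 4 splits calling as many lists. Females against males gave 7 genes under SMG against up to 1 and 13 lists against up to 12. In static culture they gave 7 genes and 6 lists, with 8 splits calling as many lists, while another split called 4044 genes and up to 14 lists were called, which points to a structure of the static libraries other than sex.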
